A study of Mus musculus with 3 samples.

How the data were processed

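The series holds 3 libraries of individual-nucleotide resolution crosslinking and immunoprecipitation (iCLIP), a method that maps where a protein touches RNA to the base. Intact thymocytes of C57BL/6 mice were irradiated with 300 mJ/cm2 of ultraviolet light, and RNA crosslinked to ZFP36L1 was pulled down with an antibody against Brf1/2, per the labels' protocols. WT cells gave 2 libraries from independent experiments, and cells of the Zfp36l1 and Zfp36l2 double conditional knockout (DCKO) gave 1. Reads were 100 nt long and came from single ends, and each primer carried a barcode of 4 random and 3 known bases, per the labels' protocols.

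The deposited data used here are a single list of 462392 stranded positions with a segment type, a gene biotype and a gene name chosen by the authors. Bowtie and the build GRCm38 are named in the submitters' processing notes, without a version or further steps. Each position carries a whole-number count with the strand as its sign, which the authors' column header calls counts and which is treated here as a score. A further deposited score is the sum of the counts within 15 nt, and recomputing it gave the same value at 100% of positions. The deposited p-value of a position equals the rank share of its extended value within its gene and segment type at 94.2% of positions, so it was not used as a test. The deposited FDR is also a score: it was listed at 0 for 103576 positions and above 1 for 3825, with a highest value of 5.53. How the authors randomised positions for it is not given in the sources used here.

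The list has 1 value per position and no library column, and which of the 3 libraries entered it is not given in the sources used here. The comparisons of WT with DCKO, the share per library, the overlap of libraries and the shift of gene lists between genotypes, all fixed before the data were examined, could therefore not be computed. Total counts per library are likewise unknown, and the counts of the pooled list sum to 814493. The design had assumed counts per library, and the tests that need them were replaced by descriptions of the pooled list. Where the design spoke of WT sites, the pooled sites were used, and no value below has a replicate error.

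A site is a position with an authors' FDR below 0.05, which left 141986 sites. Positions in the list count from 0, as shown by the segment types at coding exon edges, and coordinates below are counted from 1 on GRCm38. Genes and segments were compared with GENCODE vM21 on GRCm38.p6. Of 14592 gene names, 13631 matched a current symbol, 618 were updated from an older symbol and 343 had no match. No gene name stood at 11.6% of positions. Of the 16591 sites labelled 3′ UTR, 96.6% lay inside a GENCODE 3′ UTR of the named gene, whereas of 6719 sites labelled coding 30.5% lay in a GENCODE coding exon and 33.7% in a 3′ UTR. The authors' label was kept in the main values.

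Sequence was taken from 20 nt on either side of each site on its strand. The share of windows holding TATTTA, the core of the AU-rich element bound by the ZFP36 family, was set against 100 draws in which each site moved to a random place in the same contiguous annotated interval. The p-value is a one-sided permutation p, from positions redrawn within intervals, and 0.0099 is the smallest that 100 draws can give. Intervals of folds are 95% bootstrap intervals from 1000 draws of genes. Other patterns were TATTTAT, TTATTTATT, ATTTA, TTTTTT and all hexamers. On simulated data, sites placed at random gave a fold of 1.03, and 1599 sites planted at TATTTA among 16024 raised it to 3.67.

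For each of 20 gene lists fixed before the data were examined, the number of members with a 3′ UTR site was compared with 10000 random lists of the same size. These came from the 12541 protein-coding genes with any listed position, matched in 10 bins of the summed count outside the 3′ UTR. That sum was meant to stand in for transcript abundance. Of all listed counts, 62.9% were labelled intron, so the sum follows intron signal in large part. Matching on it does not control for mRNA abundance. The percentile is a two-sided permutation p over genes, at least 0.00020 with 10000 lists, and adjusted over the lists with Benjamini-Hochberg. Of 200 random lists of 30 genes, 3.5% had a p below 0.05, and with 15 of 30 members drawn from genes with a site 100% did. These p-values treat genes as exchangeable and measure no spread between mice or libraries.

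The genes named are Zfp36, Zfp36l1 and Zfp36l2, genes among the 20 protein-coding genes with the highest sum of counts over 3′ UTR sites, up to 3 members of each list with the highest such sum, and the 3 non-coding genes with the highest count. Others are said to be chosen after their values were seen. Shares carry 95% Wilson intervals, which cover counting error only. Windows of 50 nt on either side were compared with ribosomal RNA of the reference by blastn 2.17.0, taking alignments of at least 30 nt at 90% identity. That set holds only a piece of 28S ribosomal RNA. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Alternatives covered the site threshold, the window, the control positions, merging of sites, soft-masked sequence, the matching of lists and the ranking of genes.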

Results

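The series holds iCLIP libraries from total naive thymocytes, 2 of WT and 1 of DCKO genotype, and a single list of crosslink positions. Which of these libraries entered that list, called the pooled list here, is not given in the sources used. The list held 462392 positions with a summed count of 814493. The list does not say which library a count came from, so binding in WT and DCKO cells could not be compared, and every value describes the pooled list.

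The sites lay mainly in introns and, among the 4 segment types of protein-coding genes, were densest per kb in 3′ UTRs. Of 141986 sites, 11.7% (95% Wilson interval 11.5 to 11.9) were labelled 3′ UTR, 4.73% coding, 0.439% 5′ UTR, 64.4% intron, 16.04% intergenic and 2.66% non-coding RNA. Sites whose label and GENCODE segment were both 3′ UTR numbered 0.714 per kb of 3′ UTR, and the same count gave 0.0841 in coding sequence, 0.128 in 5′ UTRs and 0.103 in introns. The density in 3′ UTRs was thus 8.49 times that of coding sequence and 6.91 times that of introns, whereas over all listed positions these ratios were 2.28 and 5.17. The coding density keeps 30.5% of the sites labelled coding, and the 3′ UTR density 96.6% of those labelled 3′ UTR. By the authors' label alone, their threshold was passed by 37.8% of 3′ UTR positions (37.3 to 38.2), 28.8% of intron positions (28.6 to 28.9) and 19.4% of coding positions (19.0 to 19.8). Of the positions labelled coding, 2051 of 20201 in GENCODE coding exons passed, against 2265 of 5010 in GENCODE 3′ UTRs. Among sites in the upper part of the extended value, split at its median, the 3′ UTR share was 17.6%.

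**Figure D1:**
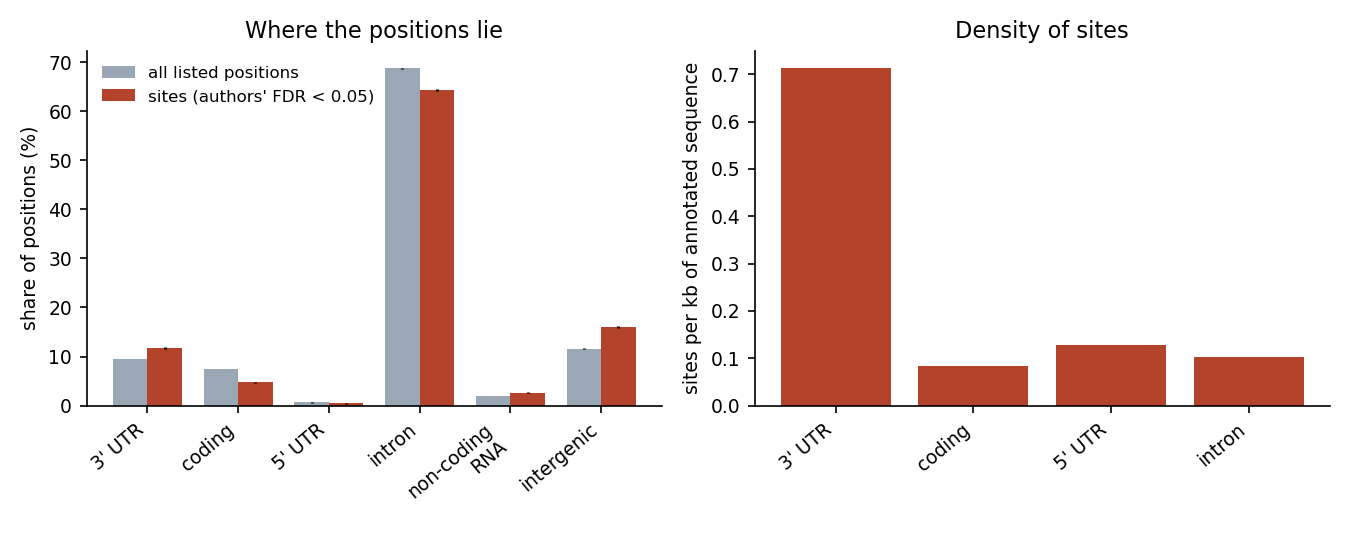
Left, share of positions (%) per segment type for all 462392 listed positions and for the 141986 sites, with 95% Wilson intervals; right, sites per kb of GENCODE sequence, counting sites whose label and GENCODE segment are the same. The 3′ UTR bar at 0.714 sites per kb stands above those of coding sequence, 5′ UTRs and introns.

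Transcripts of the ZFP36 family themselves, which encode proteins that bind AU-rich elements and promote mRNA decay, carried 3′ UTR sites. Zfp36l1 had 59 sites with a summed count of 213, rank 11 among protein-coding genes. Zfp36 had 45 sites with a summed count of 127, and Zfp36l2 had 30 sites with a summed count of 113. TATTTA lay within 20 nt of 62.2% of the Zfp36 sites, 63.3% of the Zfp36l2 sites and 35.6% of the Zfp36l1 sites. The strongest Zfp36 site, with a count of 8, was position 28376959 on the minus strand of chromosome 7 (GRCm38), in the sequence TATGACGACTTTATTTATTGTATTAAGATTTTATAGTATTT centred on it. The strongest Zfp36l2 site had a count of 24 at position 84184950 of chromosome 17, minus strand, where TATTTA began 10 nt downstream. In Zfp36l1, a site with the highest count, 10, at position 80108201 of chromosome 12, minus strand, had no TATTTA within 20 nt.

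Rag1, Bcl11b, Actb and Satb1 had the highest 3′ UTR counts, which are not adjusted for transcript abundance. In all, 2222 of 12541 protein-coding genes (17.7%) had a 3′ UTR site. Rag1, the recombinase subunit that cuts antigen receptor genes, ranked highest with 132 sites and a summed count of 1422, which was 3.36% of all 3′ UTR site counts. Bcl11b, a transcription factor of T lineage commitment, followed with 229 sites and 1413 counts. Actb, encoding cytoplasmic actin, had 79 sites and 1181 counts, and Satb1, a chromatin organiser of thymocytes, had 159 sites and 1034 counts. These 4 genes held 11.9% of the 3′ UTR site counts, and the 20 highest genes held 20.2%.

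Other genes among the 20 highest had lower summed counts. Cell surface and signalling genes were Cxcr4 (369 counts), a chemokine receptor, Cd3e (238), a subunit of the T cell receptor complex, Notch1 (223), Cd4 (191), Ptprc (166) and Stk4 (197), a kinase. Nuclear factors were Med13 (224), Cux1 (200), Ddx5 (184) and Nabp1 (167). Cdkn1b, an inhibitor of cyclin-dependent kinases, had 63 sites and 181 counts. Edem1 (260), Ywhaz (169), Lars2 (353) and Zfp36l1 were also among them. The 59 Lars2 sites all lay between positions 123461938 and 123462158 of chromosome 9, plus strand, around a sequence that resembles the conserved core of 28S ribosomal RNA. The reference set lacks that part of 28S, so whether these counts belong to Lars2 is not known.

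The strongest sites of these genes differed in their sequence. The highest Rag1 count, 110, was at position 101640502 of chromosome 2, minus strand, in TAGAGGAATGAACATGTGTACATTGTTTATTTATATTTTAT, and 75.5% of Rag1 site counts, from 26.5% of its sites, lay within 20 nt of the single TATTTA of this 3′ UTR. The share of counts near TATTTA was 83.0% in Notch1, 82.7% in Cd4, 76.3% in Med13 and 70.7% in Nabp1. It was 28.9% in Bcl11b, whose strongest site, with a count of 63, lay at position 107915160 of chromosome 12, minus strand, 9 nt before a TATTTA. In Notch1 the strongest site itself, with a count of 21, had no TATTTA within 20 nt. Actb, Cxcr4, Stk4 and Lars2 had 0 sites near TATTTA. The strongest Actb site, with a count of 45 at position 142903666 of chromosome 5, minus strand, lay in a run of thymidines, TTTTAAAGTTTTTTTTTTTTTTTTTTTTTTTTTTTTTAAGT.

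**Figure D2:**
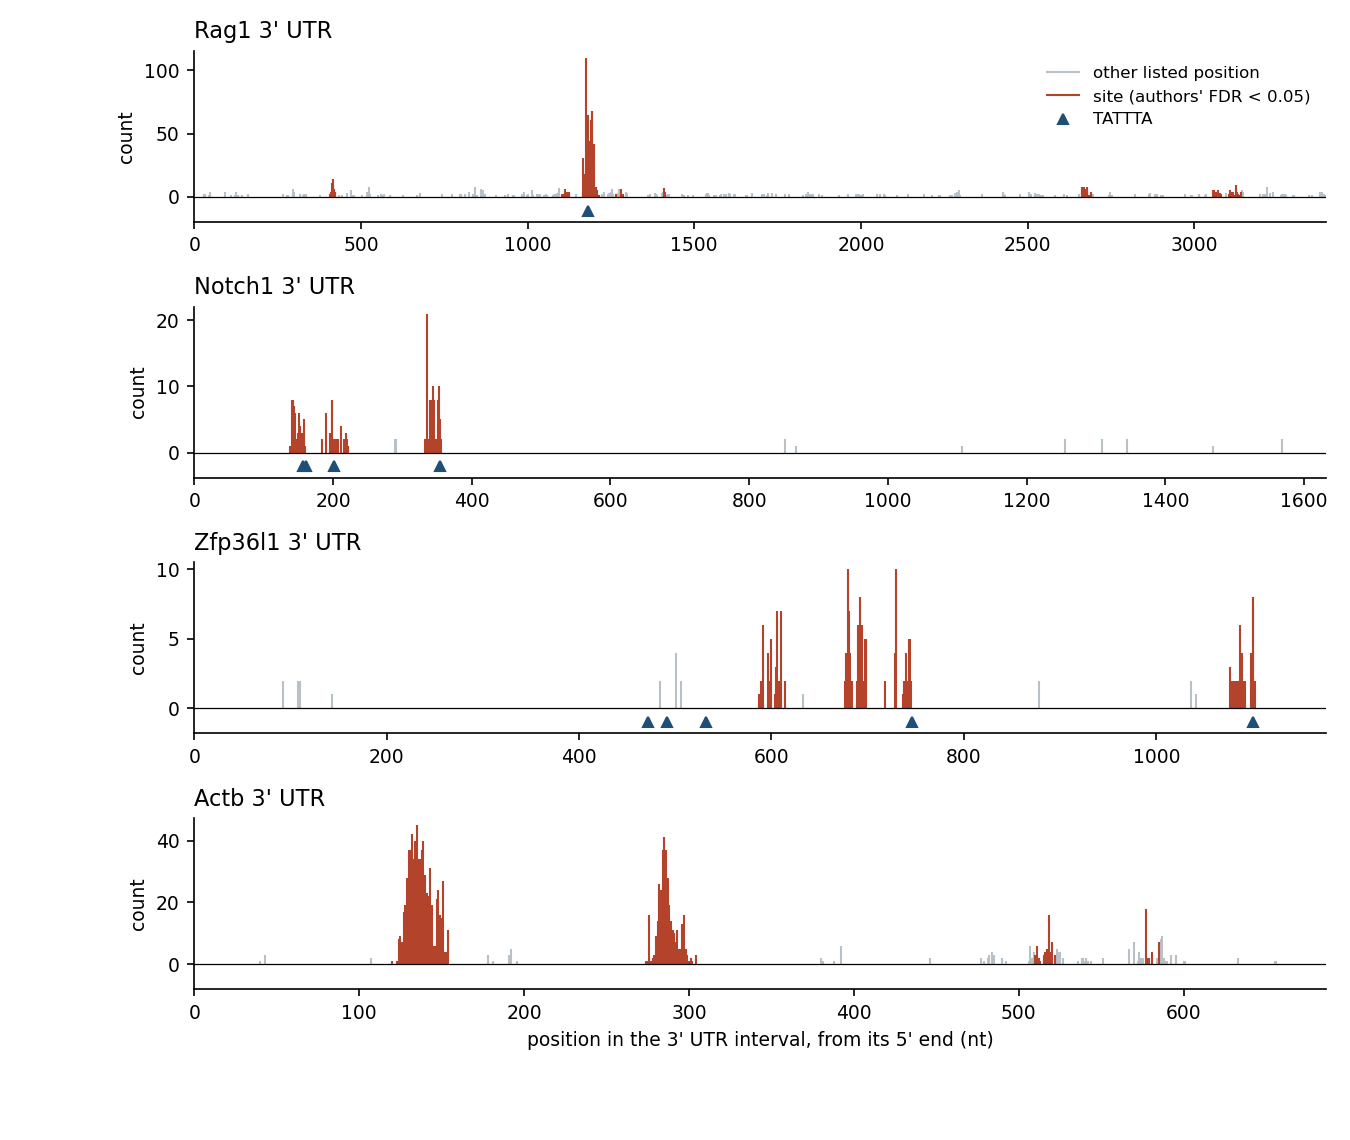
Count at each listed position (vertical axis) along the 3′ UTR intervals of Rag1, Notch1, Zfp36l1 and Actb, in nt from the 5′ end of the interval, with sites in red, other positions in grey and TATTTA as triangles. The highest Rag1 count of 110 stands 7 nt upstream of its only TATTTA, whereas the Actb interval has 0 copies of TATTTA.

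TATTTA was common near 3′ UTR sites. It lay within 20 nt of 29.0% of 16024 sites in 2151 genes, against 3.52% ± 0.158 (SD over 100 draws) of random positions in the same 3′ UTRs. The fold was 8.25 (95% gene bootstrap interval 7.65 to 8.92), with a permutation p = 0.0099, the smallest 100 draws can give. Longer forms had higher folds, 12.3 for TATTTAT (11.1 to 13.6) and 17.8 for TTATTTATT (15.2 to 21.0), and the pentamer ATTTA had a fold of 4.56 (4.30 to 4.84). TATTTA had the highest fold of 2778 hexamers, followed by ATTTAT at 8.02, and TTTTTT had 4.56 (4.21 to 4.89). The site itself was a thymidine at 65.8% of 3′ UTR sites. Against windows shuffled with their dinucleotides kept, the fold was 3.83, and with windows of 50 nt it was 4.61.

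**Figure D3:**
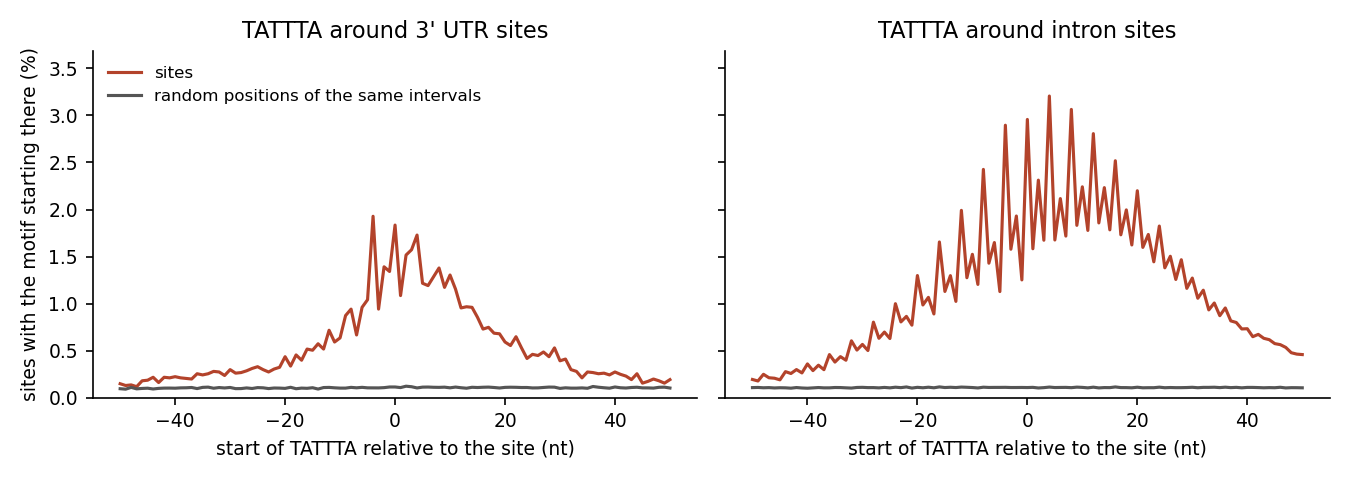
Share of sites (%) with TATTTA starting at each distance (nt) from the site, in 3′ UTRs and introns, with random positions of the same intervals in grey. The 3′ UTR share reached 1.93% at 4 nt upstream and the intron share 3.21% at 4 nt downstream, against 0.106% and 0.114% at random positions.

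The share of 3′ UTR positions near TATTTA grew with the count at the position. It was 10.1% (95% Wilson interval 9.68 to 10.6) at the 16501 positions with a count of 1 and 15.97% (15.5 to 16.5) at the 21692 with a count of 2. Counts of 3 to 4 gave 30.6% (28.9 to 32.3), counts of 5 to 9 gave 41.8% (38.9 to 44.9) and counts of 10 or more gave 50.3% (44.8 to 55.8) of 314 positions. The fold over random positions was 3.41 at a count of 1 (95% gene bootstrap interval 3.21 to 3.62) and 16.2 at 10 or more (11.5 to 23.2). The 314 positions lay in 88 genes, and the Wilson intervals treat neighbouring positions of a gene as independent. Without Rag1, Bcl11b, Actb and Satb1, the share was 10.3% at a count of 1 and 59.5% of 163 positions at 10 or more. Counts of 1 and 2 made up 50.5% and 44.0% of all listed positions, whereas a count of 3 stood at 1.88%. Part of the pool may have been counted at double weight, as set out below. The step from a count of 1 to a count of 2 therefore need not reflect stronger signal.

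**Figure D4:**
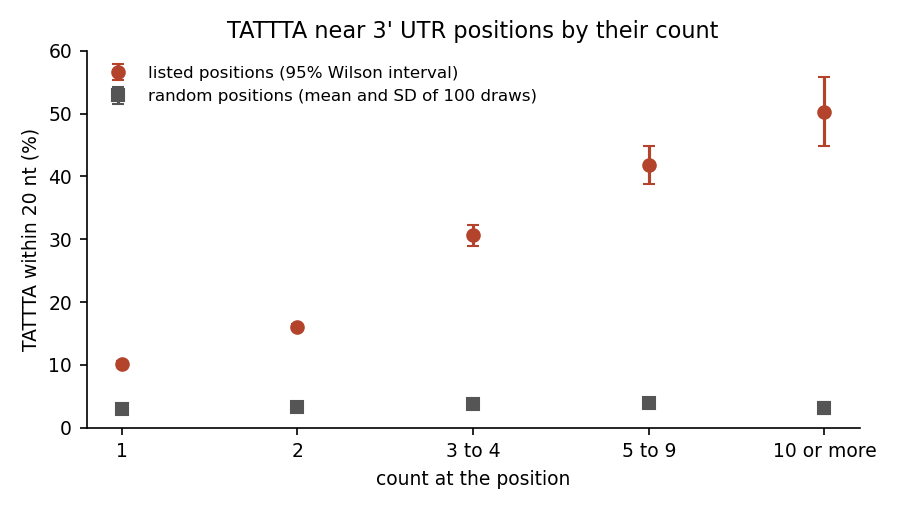
Share of listed 3′ UTR positions with TATTTA within 20 nt (%) by the count at the position, with 95% Wilson intervals, beside the mean and SD of 100 draws of random positions. The share was 10.1% at a count of 1 and 50.3% at counts of 10 or more.

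Coding sites carried TATTTA less often than 3′ UTR sites, and intron sites lay between them. The shares were 9.25% of 1956 coding sites, 8.70% of 575 sites in 5′ UTRs and 22.4% of 81614 intron sites. In Fisher's exact test (two-sided), the odds ratio of 3′ UTR against coding sites was 4.01 (p = 1.4e-92) and against intron sites 1.41 (p = 1.2e-69). These p-values count sites of a gene as independent. Against their own random positions, the fold was 3.62 in coding exons (95% interval 3.09 to 4.14), 3.84 in 5′ UTRs (1.74 to 6.44) and 7.61 in introns (7.32 to 7.91). The intron interval overlaps that of 3′ UTRs. Tandem copies (TATTTATTTA) were found at 51.1% of the intron sites with TATTTA and at 10.6% of those in 3′ UTRs. Soft-masked sequence held 59.4% of the 3′ UTR sites and 75.4% of the intron sites. Of 18386 intron sites with TATTTA, 2100 lay outside it. Outside soft-masked sequence, TATTTA lay near 31.3% of 3′ UTR sites, a fold of 8.57. There it lay near 10.4% of intron sites, a fold of 4.05 against positions 60 to 300 nt away. Among sites in the upper part of the extended value the odds ratio was 2.14 against coding sites and 1.06 against intron sites.

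Genes of the T cell programme had 3′ UTR sites more often than matched genes. T lineage transcription factors had a site in 23 of 36 measured members against 13.5 in matched lists (1.70 times, adjusted permutation p = 0.00560). Besides Bcl11b and Satb1, Sox4 had 55 sites and 136 counts, and Gata3, Ets1, Ikzf1, Lef1, Tcf7, Runx1 and Myb each had at least 22 sites, named after their values were seen. Pre-TCR and TCR signalling genes had a site in 26 of 45 (1.60 times, adjusted permutation p = 0.00560), led by Cd3e, Ptprc and Nfkbia, an inhibitor of NF-kappaB with 41 sites and 146 counts. With all listed positions in place of sites, the latter list had an adjusted permutation p of 0.0896. Thymocyte stage markers had a site in 17 of 31 (1.82 times, adjusted permutation p = 0.00743), led by Rag1, Satb1 and Cxcr4. Without matching on signal, the excess of these 3 lists was 3.61, 3.27 and 3.09 times, and over all listed positions 1.31, 1.19 and 1.49 times. Abundant housekeeping mRNAs had a similar excess, 1.80 times. With 3′ UTR length matched as well, they had 2.57 times, against 1.69, 1.90 and 1.96 for these lists. Matched on coding counts alone, they had 1.34 times, against 2.24, 1.98 and 1.88. The excess is therefore not shown to be particular to T cell genes.

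Messenger RNAs known for AU-rich elements showed the largest excess over genes matched on signal among the lists past the threshold. Classical AU-rich cytokine and immediate early genes had a site in 16 of 34 measured members against 4.28 in matched lists, 3.74 times as many (adjusted permutation p = 0.00200). Its leading members were Nfkbia, Ets2 with 44 sites and 117 counts, and Btg2, an antiproliferative factor that recruits deadenylases, with 37 sites and 107 counts. Genes of the ZFP36 family and other AU-rich or stem-loop binding proteins had a site in 16 of 23 (2.08 times, adjusted permutation p = 0.00533). Without matching, the excess was 2.65 times for the AU-rich list, lower than the 3.93 times of this list. Among them, Elavl1, which encodes the AU-rich binding protein HuR, had 40 sites and 131 counts, 77.5% of its sites near TATTTA. Deadenylation and decay genes had a site in 18 of 34 (1.57 times, adjusted permutation p = 0.0440), with Tnrc6b at 47 sites and Ddx6 at 30. That list did not pass with an authors' FDR below 0.01 (adjusted permutation p = 0.144) or over all listed positions (0.903). TATTTA lay near 45.9% of the Btg2 sites, 8.51% of the Tnrc6b sites and 0% of the Ddx6 sites.

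Cell cycle regulators had a site in 19 of 48 (1.81 times, adjusted permutation p = 0.0135). Cdkn1b led, followed by Top2a, a DNA topoisomerase, with 17 sites and 68 counts, and Ccnd3, a cyclin of thymocyte proliferation, with 20 sites and 53 counts. TATTTA lay near 28.6% of the Cdkn1b sites, 100% of the Top2a sites and 0% of the Ccnd3 sites. Apoptosis regulators had a site in 12 of 29 (1.73 times, adjusted permutation p = 0.0698), among them the survival factors Bcl2l1 with 26 sites and 133 counts and Mcl1 with 39 sites and 96 counts, and Pdcd4 with 34 sites and 87 counts. That list passed with GENCODE 3′ UTRs (adjusted permutation p = 0.0264), without matching (0.00831), matched on coding counts (0.0320) and over all listed positions (0.00600). It did not pass with an authors' FDR below 0.01 (adjusted permutation p = 0.142). Nor did it pass with 3′ UTR length matched together with signal (0.113) or with coding counts (0.0563). TATTTA lay near 65.4% of the Bcl2l1 sites, 64.1% of the Mcl1 sites and 0% of the Pdcd4 sites. Notch pathway genes had a site in 10 of 22 (1.55 times, adjusted permutation p = 0.194), with Notch1, Notch3 (10 sites) and Ncstn (7 sites) leading. PI3K, mTOR and growth signalling genes had a site in 13 of 33 (1.14 times, adjusted permutation p = 0.817), led by Hif1a with 27 sites and 155 counts, Gsk3b with 30 sites and Stat5b with 24 sites. Without matching, the Notch and PI3K lists each had an adjusted permutation p of 0.00800, and matched on coding counts the Notch list had 0.0320. Neither list passed under any other alternative.

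The DNA damage response and p53 list had a site in 11 of 49 measured members against 13.3 in matched lists (0.825 times, adjusted permutation p = 0.720). Without matching, the ratio turned to 1.27 (adjusted permutation p = 0.560). The highest members were Mdm2, the ubiquitin ligase of p53, with 26 sites and 60 counts, Lig4 with 19 sites and 41 counts, and Hipk1 with 16 sites and 31 counts. Trp53inp1 and Ccng2 of this list, named after their values were seen, had 124 sites (362 counts) and 39 sites (161 counts) that the authors labelled coding and that lie in GENCODE 3′ UTRs.

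Ribosomal protein and oxidative phosphorylation genes had a 3′ UTR site less often than genes matched on signal. A site was found in 2 of 77 ribosomal protein genes, Rps9 and Rps3, against 10.01 (adjusted permutation p = 0.00733), and in 1 of 83 nuclear genes of oxidative phosphorylation, Ndufb2, against 10.8 (adjusted permutation p = 0.00200). Neither list passed when 3′ UTR length was matched together with the signal (0.413 and 0.177 times, adjusted permutation p = 0.338 and 0.0827). Both passed when coding counts and length were matched (adjusted permutation p = 0.0388 and 0.0280). The ratios, 0.1998 and 0.0925, were 0.350 and 0.241 with GENCODE 3′ UTRs and 0.525 and 0.652 over all listed positions. Abundant housekeeping mRNAs had a site in 14 of 34 (1.80 times, adjusted permutation p = 0.0440), led by Actb, Pfn1 with 39 sites and Tubb5 with 35 sites, and did not pass when matched on coding counts (adjusted permutation p = 0.387) or over all listed positions (0.0755).

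The lists of marker genes of other cell types were too small to test whether they had a 3′ UTR site less often than matched genes. None was found for the measured markers of B cells (8 genes), myeloid cells (10), erythroid cells (6) or NK and innate lymphocytes (8), where matched lists gave 0.421, 0.812, 0.309 and 0.462 genes (adjusted permutation p = 1 for each). Thymic epithelial markers had a site in 2 of 9 genes, Epcam and Ly75, each with a summed count of 4 (3.03 times, adjusted permutation p = 0.367). Stromal and endothelial markers had a site in 3 of 10 (2.59 times, adjusted permutation p = 0.194): Thy1, which thymocytes also express, with 39 sites and 154 counts, Pecam1 with 8 sites and Col1a1 with 2.

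**Figure D5:**
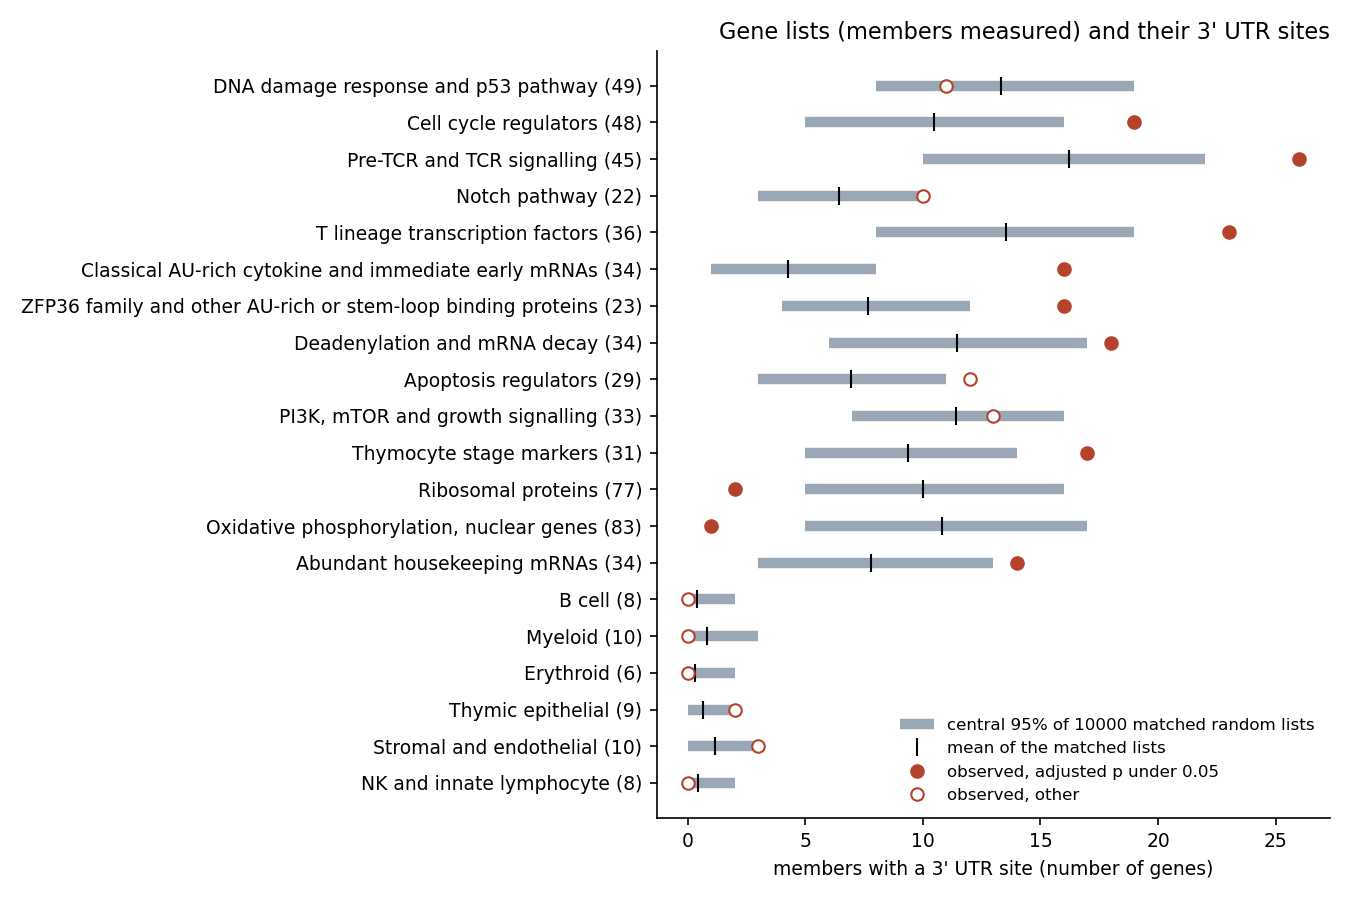
Number of members with a 3′ UTR site for each of the 20 gene lists (points), with the mean and central 95% of 10000 matched random lists (ticks and bars) and the number of measured members in brackets. Filled points mark the 10 lists with an adjusted p below 0.05, of which ribosomal protein and oxidative phosphorylation genes lie to the left of their bars.

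Non-coding RNA took a small share of positions and a larger share of counts. Sites labelled non-coding RNA held 9.10% of the site counts, and 55.9% of those counts lay in windows matching ribosomal RNA. The non-coding genes with the highest counts were Gm26924 with 17350, Malat1 with 6285 and the mitochondrial large-subunit ribosomal RNA gene mt-Rnr2 with 4507. Genes labelled ribosomal RNA held 5982 counts (mitochondrial) and 304 (other), whereas 18096 non-coding site counts matched ribosomal RNA. Part of the matches thus lay in genes with other labels. Gm26924 is labelled a long non-coding RNA, and whether its counts are ribosomal was not tested per gene. Malat1, a nuclear long non-coding RNA, had 1530 listed positions, and its highest count was 64.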

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

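In this part, the tests of independent counting, of a component at double weight and of clipped spliced reads were chosen after the result was seen, as was the stratification of pyrimidine tracts within introns, which was added after the pooled ratio. No group of 4 or more libraries exists, so single libraries could not be compared for outlying values, and 3 signals outside the comparisons of the 3′ UTR sites stood out. Of 22780 intergenic sites, 14.3% had TATTTA within 20 nt against 2.55% of positions 60 to 300 nt away, a fold of 5.62 that was 2.89 at the 7073 intergenic sites outside soft-masked and ribosomal sequence. The last base of internal exons held 1770 listed positions. Of the sites the authors labelled coding, 2265 lay in a GENCODE 3′ UTR, with Trp53inp1, Sdccag3 (31 sites, 175 counts) and Pan3 (43 sites, 133 counts) among the genes, named after their values were seen.

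The frequency of TATTTA near 3′ UTR sites was set against sequence and chemistry. Random positions of the same 3′ UTRs, the comparison that defines the fold of 8.25, remove the composition of whole 3′ UTRs only. Against windows shuffled with their own dinucleotides the fold was 3.83, so local composition may account for part of the frequency and not for all of it. A preference of ultraviolet crosslinking for uridine was expected to raise the fold of TTTTTT as much, yet that fold was 4.56, lower by 3.69. The SD of 0.389 from the draws moves each site separately and leaves out their clustering. The gene bootstrap intervals, 7.65 to 8.92 and 4.21 to 4.89, did not overlap. However, TTTTTT lay near 31.8% of 3′ UTR sites against 6.96% of random positions, and TATTTA near 29.0% against 3.52%. TTTTTT was thus more common near sites than TATTTA, and its lower fold goes with a higher share at random positions. The folds alone therefore cannot say how much of the TATTTA excess this preference explains. In the hexamer ranking of introns the folds were closer, 7.65 for TATTTA and 6.83 for TTTTTT. Binding by ZFP36L1 or ZFP36L2 is a candidate explanation. A comparison with the DCKO library would bear on it, but this explanation stays untested here because counts are not split by library.

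Positions with a count of 1 (233562) and of 2 (203639) were nearly as frequent, while 8707 had a count of 3. Independent counting of molecules at each position requires that 3 times the ratio of counts of 3 to counts of 2, which was 0.128, be no lower than 2 times the ratio of counts of 2 to counts of 1, which was 1.74. A fixed property of the location, such as mappability, needs neighbours within 15 nt to share their count in over 90% of pairs, and 60.9% of 91635 pairs did, against 51.01% after shuffling. A part of the pool counted at double weight may account for the pattern: positions with a count of 4 were 1.96 times the geometric mean of those with 3 and 5, the excess recurred at 6 (1.54) and 8 (1.34), and the share of 2 among counts of 1 and 2 was 56.8% in 3′ UTRs, 46.3% in introns and 31.5% between genes. Which library such a part would be stays open, and no biological explanation was tested.

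Exon edges showed a further pattern. The last exon base held 9.90 times the mean of its flanks, and positions peaked 12 nt before exons (1689 positions against 593 at 50 nt). Clipping of spliced reads at both edges would raise the last intron base too, which held 0.319 of its flanks. Those flanks include part of the rise before exons (1549 positions at 11 nt), which lowers this ratio. The last intron base held 114 positions, between 51 at the base before it and 138 at the first exon base. A preference for AGGT sequence would mark other AGGT of the same genes, where the rate was 75.4 times lower, or 24.2 times lower within exons alone. Pyrimidine tracts before exons held 4.13 times (jackknife SE 0.115 over chromosomes) the positions of other tracts, within introns, and 5.31 times without that stratification, so a plain preference for pyrimidines cannot be told apart from binding near splice sites, since tracts were not matched on uridine content. Reads that begin at the 5′ end of excised introns may be the source of the exon-end peak, but neither this nor any biological explanation was tested.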

How the results depend on the processing

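Alternatives of the 3′ UTR share by all listed positions, GENCODE label or removal of ribosomal matches were chosen after seeing the data, as were those of the motif by all listed positions, count class, local controls, annotation or 4 genes left out, and those of the lists by coding counts, annotation or all positions, and 3 of the 4 rankings. The 3′ UTR share of 11.7% moved beyond its interval to 12.9% at an FDR below 0.01, 17.6% in the upper part of the extended value, 11.9% by counts, 14.8% in protein-coding genes, 9.49% over all listed positions and 13.3% with GENCODE labels; the cause was not tested. The fold of TATTTA stayed above 1 and past the threshold in 13 alternatives (3.41 to 10.6), as did both odds ratios under 4 alternatives each, although the ratio against introns fell from 1.41 to 1.06 in the upper part of the extended value, where its p treats sites of a gene as independent. The lists above matched genes stayed within 1.5 times their number, while those below went from 2 to 0 when 3′ UTR length was matched as well, where ratios were 0.413 and 0.177. Of 140 values of single lists, 126 kept their side of the threshold, 7 lost it and 7 gained it. The 126 include all 7 values of each of the 6 cell type lists. Those lists had 6 to 10 measured genes and little room to cross the threshold. Of the 20 highest genes, 15 stayed when ranked by number of sites, 17 with GENCODE labels, 18 over all positions and 19 with counts halved and rounded up. No paired analysis was possible because the deposited values carry no library. For the same reason TMM, DESeq2, low-count filters, overlap distances, leaving out a WT library, sites with signal in both WT libraries and gene changes from 3′ UTR sites alone were not run. Depth per library is unknown, and whether genes with few counts lack sites for that reason was not tested.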

Other observations

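By intron site counts, a ranking chosen after the values were seen, the highest protein-coding genes were Cdk8 (3998), Satb1 (2004), Cmss1 (1843), Themis (1264), a regulator of thymocyte selection, Ccnd3 (1242), Camk4 (1126), Hdac7 (973) and Camk1d (958). Satb1 had 872 intron sites with a highest count of 17, so its signal was spread, whereas 3985 of the Cdk8 counts lay between positions 146260991 and 146261340 of chromosome 5, plus strand. For Cmss1, 1828 of 1843 counts lay between positions 57391457 and 57391680 of chromosome 16, minus strand. The strongest Lars2 site lies in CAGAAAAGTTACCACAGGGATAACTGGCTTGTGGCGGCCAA at position 123461965 of chromosome 9, which resembles the conserved core of 28S ribosomal RNA. None of the counts of these 4 genes (Lars2, Cdk8, Cmss1 and Camk1d) matched the ribosomal set used here, which holds 28S only in part and lacks that core, so a ribosomal origin of these counts was not tested, and 0 of the Lars2 counts, 13 of the Cdk8 counts, 8 of the Cmss1 counts and 314 of the Camk1d counts lay in soft-masked sequence.

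Sites were spread unevenly along 3′ UTR intervals of at least 500 nt. Of 15123 sites, 26.2% (95% Wilson interval 25.5 to 27.0) lay in part 1 of 5 equal parts, nearest the stop codon, 14.03% (13.5 to 14.6) in part 4 and 21.3% (20.7 to 22.0) in part 5, nearest the 3′ end. TATTTA lay near 34.7% of the sites in part 5 and near 28.3% in part 1. Among intergenic sites without a ribosomal match, 4.60% lay within 1000 nt downstream of an annotated 3′ UTR and 76.7% lay more than 20000 nt away or had none upstream.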
